A study of Homo sapiens with 28 samples.

How the data were processed

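RNA was sequenced from human skeletal muscle in 4 groups of samples: before exercise and 4 hours after exercise on the day that followed a day of normal activity, and before and 4 hours after exercise on the day that followed a day of inactivity. The groups are called active pre, active post, inactive pre and inactive post. The labels describe 28 samples, 7, 7, 6 and 8 in these groups. Columns were matched to 25 of them by name (6, 6, 6 and 7); active pre 11, active post 9 and inactive post 5 were not analysed here. Per the labels' protocols, RNA was purified on RNeasy columns with a DNase step and libraries were made with NEBNext Ultra II Directional reagents, which mark the strand. How mRNA was enriched, and whether reads were counted by strand, is not given in the sources used here. Genes that overlap another gene or lie antisense to one are therefore uncertain where named.

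The authors deposited 2 tables of counts, 1 for each day, with whole numbers per gene and library and Ensembl gene IDs. Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR 2.5.3a, RSEM, edgeR 4.0.16 and the build GRCh38.p10 were named, with no role or order. RSEM gives estimated counts, so the deposited counts may have been rounded by the authors before deposit, and reads shared by near-identical genes may have been split between them. For normal activity 15463 genes were given in 12 libraries and for inactivity 15506 genes in 13. Both tables held 15260 genes, and 203 and 246 were in 1 table alone. The filter the authors applied is not given in the sources used here, but in each table every gene reached its 6th-highest count at or above 0.250 (inactivity) or 0.255 (normal activity) CPM. All values that enter the tests are unnormalised counts, so libraries of both tables were fitted together over the 15260 shared genes. Symbols came from a gene name table for 15180 gene IDs and otherwise from GENCODE release 29, which also gave coordinates on GRCh38. These are the ends of whole genes, since the counts do not resolve exons.

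Total counts ranged from 27.5 to 112.2 M (SI prefix mega) per library, with a median of 37.4 M. The genes of the mitochondrial genome took 10.1 to 19.4% of counts and the 10 most abundant genes 21.5 to 26.5%. No label gives a sequencing batch or date, so none could be tested. Among the 66 pairs of libraries within a group, the lowest chi-square per degree of freedom was 61.5, so no library looked like a second copy of another. The labels carry a number in each sample name, 9 numbers in all, without saying what it stands for. Deviations from the group means correlated in all 27 same-numbered pairs, from r = 0.179 to r = 0.581 with a median of 0.392 across genes, against a median of −0.0537 in 207 other pairs, and 23 of the 24 libraries with a partner correlated best with a library of their own number. All 27 lay over the limit of 0.1 fixed for this check, so the numbers were taken to pair the samples; this pairing comes from the values, not from a label. Nothing in the labels says that samples of a group came from separate people, so p-values measure the spread between these samples.

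Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 10, which kept all 15260 genes). All 25 libraries entered 1 fit of 4 groups with no block. Contrasts were post minus pre on each day, the difference of these 2 responses, and inactive minus active before and after exercise. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and adjusted p-values of single genes are from this test unless another is named. Log2 fold changes are fitted values with edgeR's default prior count and are given ± their standard error, taken from the unshrunk fit. Log2 CPM of single libraries have a prior count of 2, and CPM are scaled by TMM. No shared controls link the 2 exercise responses.

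Gene lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the 31 lists of a comparison. The 20 pathway lists were immediate early genes, fat oxidation and PPAR targets, regulators of mitochondrial biogenesis, nuclear and mitochondrial-genome genes of oxidative phosphorylation, glucose uptake and glycolysis, insulin signalling, atrophy, autophagy, heat shock, angiogenesis, cytokines and inflammation, the circadian clock, metallothionein and redox genes, myogenic regulators, the sarcomere load response, extracellular matrix, ATF4 and endoplasmic reticulum (ER) stress, glucocorticoid targets and cytosolic ribosomal proteins. The 11 marker lists were slow fibre, fast fibre, endothelial, fibroblast, adipocyte, macrophage and monocyte, neutrophil, erythrocyte, T cell, smooth muscle and pericyte, and keratinocyte. In all, 1 Y-linked list member was left out. Lists overlap little: atrophy shares 2 genes with insulin signalling, 2 with myogenic regulators and 1 each with autophagy and glucocorticoid targets; extracellular matrix shares 3 with fibroblast; fat oxidation shares 1 with angiogenesis and 1 with glucocorticoid targets; heat shock and ER stress, angiogenesis and endothelial, and glucocorticoid targets with cytokines, the clock and metallothioneins share 1 each.

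The groups, contrasts, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule took the 10 largest rises and falls among called genes with a symbol and an average log2 CPM of at least 1, the 5 smallest p where no gene passed, the 10 smallest p in each direction for the difference, and the 3 members of each list with the smallest p, leaving out Y-linked genes and XIST. Not every gene it took is reported here. For each named gene, libraries of the later or inactive group were counted that lay on the called side of the mean of the reference group. Alternatives were DESeq2 1.42.0, upper-quartile factors, no filter, the replicate number as a block, complete pairs, the samples of the contrast alone, each number left out, other thresholds, and rank-based camera. After the values were seen, each library was left out in turn and 3 libraries that stood apart in markers of other cells (active pre 4, active post 11 and inactive post 4, picked by eye) were left out together and singly. Upper-quartile and DESeq2 scaling changed the sign of the median of no list that camera called.

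The pipeline was tested on counts simulated from the real means and library sizes for 15260 genes, 200 of them changed. For the response after normal activity it recovered 37.8% of genes changed by 1.5-fold, 64.1% by 2-fold and 93.5% by 4-fold, and for the response after inactivity 27.3, 69.4 and 96.8%. For the difference of the responses these shares were 5.41, 43.3 and 88.1%, before exercise 20.3, 60.3 and 96.2%, and after exercise 36.8, 72 and 94.1%. False calls numbered 7, 4, 3, 5 and 6. The simulation holds no differences between replicate numbers, so these shares do not cover them. A list of 19 members raised 1.5-fold was found (adjusted p = 1.47e-23), with 1 of 30 other lists called.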

Results

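The data were counts of RNA-seq reads per gene from human skeletal muscle, before exercise (pre) and 4 hours after it (post), following a day of normal activity (active) or of inactivity (inactive). Libraries numbered 6 in active pre, 6 in active post, 6 in inactive pre and 7 in inactive post. Total counts, in M (SI prefix mega), had group medians of 38.2, 35.1, 39.6 and 37.3 M. They ranged from 33.6 to 61.4, from 32.5 to 61.6, from 33.2 to 112.2 and from 27.5 to 69.8 M. The comparisons ask how muscle transcripts differed after exercise on each day, whether the response depended on the activity of the day before, and whether muscle differed between the days before or after exercise. No group was sampled 4 hours later without exercise. Effects of the time of day or of the hours between samples therefore cannot be told apart from those of exercise. The exercise response here means post against pre.

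Exercise after a day of normal activity was followed by higher transcripts of NR4A3, PPARGC1A, HK2, PDK4 and VEGFA, and by lower transcripts of the clock repressors NR1D1 and PER1. NR4A3, an orphan nuclear receptor induced by exercise, rose from 5.06 ± 6.58 to 415 ± 280.1 CPM (SD, n = 6 and 6), a log2 fold change of 6.36 ± 0.91 (adjusted p = 0.000119). PPARGC1A, a coactivator of mitochondrial gene expression, rose from 35.2 ± 9.44 to 455 ± 215 CPM (3.69 ± 0.38, adjusted p = 2.28e-06). HK2, the hexokinase that phosphorylates glucose in muscle, rose from 11.7 ± 9.26 to 130.1 ± 108 CPM (3.48 ± 0.59, adjusted p = 0.000663). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose from 94.5 ± 86.4 to 807 ± 380.2 CPM (3.09 ± 0.66, adjusted p = 0.00441).

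VEGFA, a growth factor of blood vessels, rose from 149 ± 43.3 to 535 ± 172 CPM (1.85 ± 0.28, adjusted p = 0.000226). The clock repressors NR1D1 and PER1 fell. NR1D1 went from 65.2 ± 10.1 to 18.9 ± 5.71 CPM (−1.78 ± 0.21, adjusted p = 1.18e-05) and PER1 from 189 ± 41 to 59.5 ± 19.9 CPM (−1.67 ± 0.23, adjusted p = 8.23e-05).

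Positions are on GRCh38, with GENCODE 29 gene ends. NR4A3 is ENSG00000119508, chromosome 9, 99821855 to 99866891. PPARGC1A is ENSG00000109819, chromosome 4, 23755041 to 23904089, and HK2 is ENSG00000159399, chromosome 2, 74833981 to 74893359. PDK4 is ENSG00000004799, chromosome 7, 95583499 to 95596491, and VEGFA is ENSG00000112715, chromosome 6, 43770184 to 43786487. NR1D1 (ENSG00000126368, chromosome 17, 40092787 to 40100725) and PER1 (ENSG00000179094, chromosome 17, 8140472 to 8156506) lie on the same chromosome. For NR4A3, PPARGC1A, HK2, PDK4 and VEGFA, 6 of 6 active post libraries lay above the highest active pre library. For NR1D1 and PER1 6 of 6 lay below the lowest.

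**Figure D1:**
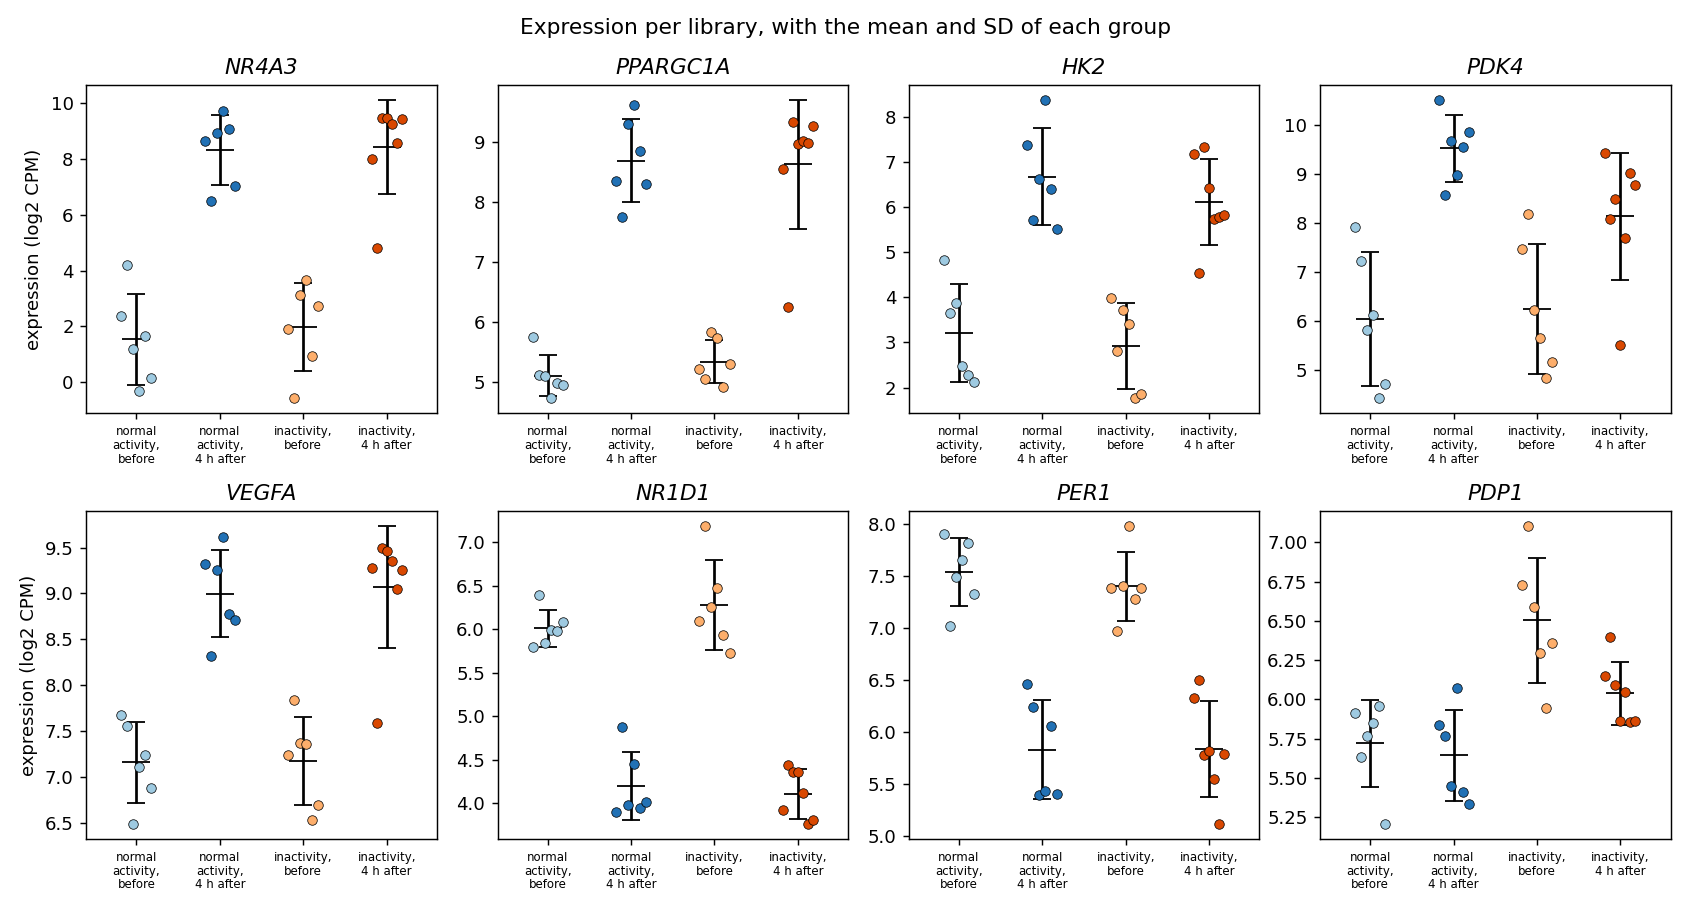
Log2 CPM of 8 genes in each library (points, 1 per library) with the group mean and SD (bar) for active pre, active post, inactive pre and inactive post (n = 6, 6, 6 and 7). NR4A3 rose from a mean of 5.06 CPM to 415 CPM after exercise on the active day, while PDP1 had means of 53.5 CPM in active pre and 93.7 CPM in inactive pre.

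Of 15260 genes tested with edgeR's quasi-likelihood test, 1084 changed, 743 upward and 341 downward, with 271 and 69 of these by at least 2-fold. The share of rises was 68.5% with TMM and 57.0% with upper-quartile factors. Beside NR4A3, the largest rises were in MAFF (5.54 ± 0.80, adjusted p = 0.000133), a small Maf transcription factor, SLC16A6 (4.42 ± 0.70, adjusted p = 0.00032), a monocarboxylate transporter, and PRODH (4.04 ± 0.61, adjusted p = 0.000222), which starts proline breakdown in mitochondria. They were followed by PRKAG2 (3.87 ± 0.31, adjusted p = 5.82e-08), a subunit of the energy sensor AMPK, and SLC30A2 (3.55 ± 0.45, adjusted p = 3.26e-05), a zinc transporter. The kinase gene SIK1 (3.77, adjusted p = 0.00634) and its near-identical copy SIK1B (3.55, adjusted p = 0.0006) also rose. Their separate values are uncertain because they share reads. The largest falls were in GADD45G (−2.05 ± 0.48, adjusted p = 0.00899), a growth arrest gene, DENND2C (−1.89 ± 0.21, adjusted p = 5.24e-06) and SLC1A7 (−1.83 ± 0.36, adjusted p = 0.00247), a glutamate transporter. The basic helix-loop-helix factors TCF15 (−1.80 ± 0.26, adjusted p = 0.000119) and HES1 (−1.79 ± 0.25, adjusted p = 9.56e-05) fell too. GLCCI1 (−1.71, adjusted p = 0.000239), named for its induction by glucocorticoids, and GAB1 (−1.67, adjusted p = 0.000133), an adaptor of growth factor receptors, fell as well. AC002996.1 fell by 1.81 on the log2 scale (adjusted p = 0.0462). That call was lost with the replicate block (adjusted p = 0.174) and held in 5 of 18 alternatives, whose adjusted p ranged from 0.0113 to 0.447.

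Immediate early genes, which cells switch on soon after a stimulus, ranked higher than other genes, with adjusted p = 0.0126 by camera and adjusted p = 0.611 with an estimated correlation. Of 20 measured members 6 rose, 1 fell and 13 did not pass, and 10 rose and 2 fell adjusted over the list alone. NR4A3, NR4A1 (2.54, adjusted p = 0.00302) and JUNB (1.76, adjusted p = 0.00346) were among the rises. Angiogenesis genes had the smallest list p, with adjusted p = 1.13e-05 by camera and adjusted p = 0.235 with an estimated correlation. Of 16 measured members 8 rose, 0 fell and 8 did not pass, and 8 rose and 0 fell adjusted over the list alone. VEGFA was joined by ANGPT2 (1.68, adjusted p = 0.000854), an angiopoietin, and KDR (1.27, adjusted p = 0.000879), the main VEGF receptor. Clock genes ranked lower, with adjusted p = 0.00187 by camera and adjusted p = 0.235 with an estimated correlation. Of 19 measured members 3 rose, 8 fell and 8 did not pass, and 4 rose and 9 fell adjusted over the list alone. The clock repressor CIART (−1.25, adjusted p = 6.79e-05) fell beside NR1D1 and PER1. Cytokine and inflammation genes moved both ways (camera adjusted p = 0.204). Of 12 measured members 3 rose, 1 fell and 8 did not pass, and 4 rose and 1 fell adjusted over the list alone. Examples were IL6R (1.87, adjusted p = 0.000227), the interleukin 6 receptor, CCL2 (1.5, adjusted p = 0.0207), a chemokine, and NFKBIA (−1.09, adjusted p = 0.00837), an inhibitor of NF-kappaB.

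Regulators of mitochondrial biogenesis ranked higher, with adjusted p = 0.00599 by camera and adjusted p = 0.431 with an estimated correlation. Of 15 measured members 6 rose, 0 fell and 9 did not pass, and 6 rose and 1 fell adjusted over the list alone. The rises included PPARGC1A, PERM1 (1.19, adjusted p = 0.00173), a muscle regulator induced by it, and PPRC1 (0.81, adjusted p = 0.00604), a related coactivator. Nuclear genes of oxidative phosphorylation, which encode the respiratory chain itself, ranked lower, with adjusted p = 0.0126 by camera and adjusted p = 0.764 with an estimated correlation. None of 78 measured members changed, and 0 rose and 0 fell adjusted over the list alone. Only 4 of them had a positive fold change, and the median was −0.08. COX6A1 was at 0.33, NDUFC1 at −0.19 and ATP5F1C at −0.22. Genes of the mitochondrial genome also ranked lower, with adjusted p = 0.0253 by camera and adjusted p = 0.639 with an estimated correlation. None of 13 measured members changed, and 0 rose and 0 fell adjusted over the list alone. Their median was −0.21. Fat oxidation genes and PPAR targets ranked higher, with adjusted p = 0.025 by camera and adjusted p = 0.639 with an estimated correlation. Of 23 measured members 3 rose, 0 fell and 20 did not pass, and 5 rose and 0 fell adjusted over the list alone. The rises were PDK4, ANGPTL4 (3.32, adjusted p = 0.0133), an inhibitor of lipoprotein lipase, and PPARD (0.98, adjusted p = 0.0187). With the replicate block these last 3 calls were lost. Adjusted p was then 0.447 for nuclear oxidative phosphorylation (range over the 7 alternatives 0.00112 to 0.764), 0.341 for the mitochondrial genome (0.00533 to 0.639) and 0.0966 for fat oxidation (0.00857 to 0.639).

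Glucose uptake and glycolysis genes were not called (camera adjusted p = 0.236, median −0.000737, mean 0.29, upward test). Of 27 measured members 2 rose, 0 fell and 25 did not pass, and 2 rose and 0 fell adjusted over the list alone. The rises were HK2 and PFKFB2 (2.06, adjusted p = 0.00106), which makes an activator of glycolysis. The replicate block called this list (adjusted p = 0.0251, range over the 7 alternatives 0.0251 to 0.764, and adjusted p = 0.662 with an estimated correlation under the block). Insulin signalling genes were not called either (camera adjusted p = 0.0683). Of 17 measured members 3 rose, 1 fell and 13 did not pass, and 3 rose and 1 fell adjusted over the list alone. The rises were FOXO1 (2.14, adjusted p = 8.12e-05), IRS2 (2.16, adjusted p = 0.000682) and RHEB (0.65, adjusted p = 0.00163). Atrophy genes ranked higher, with adjusted p = 0.00276 by camera and adjusted p = 0.355 with an estimated correlation. Of 14 measured members 4 rose, 1 fell and 9 did not pass, and 4 rose and 1 fell adjusted over the list alone. The rises included FOXO1, CDKN1A (1.78, adjusted p = 0.00137), a cell cycle inhibitor, and TRIM63 (1.99, adjusted p = 0.0021), a muscle ubiquitin ligase. In the autophagy list (camera adjusted p = 0.242) GABARAPL1 (0.93, adjusted p = 0.00361) rose. Of 14 measured members 1 rose, 0 fell and 13 did not pass, and 1 rose and 0 fell adjusted over the list alone.

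Stress genes ranked higher as well. Heat shock genes did so with adjusted p = 0.0182 by camera and adjusted p = 0.611 with an estimated correlation. Of 15 measured members 2 rose, 0 fell and 13 did not pass, and 4 rose and 1 fell adjusted over the list alone. The rises were HSPA5 (0.33, adjusted p = 0.0194), the ER chaperone, and HSPA1A (0.71, adjusted p = 0.0273), uncertain beside its near-identical copy HSPA1B. ATF4 and ER stress genes followed, with adjusted p = 0.0409 by camera and adjusted p = 0.469 with an estimated correlation. Of 10 measured members 3 rose, 0 fell and 7 did not pass, and 4 rose and 0 fell adjusted over the list alone. HSPA5, DDIT3 (1.03, adjusted p = 0.00381) and XBP1 (0.42, adjusted p = 0.0432) rose. Metallothionein and redox genes were higher in rank, with adjusted p = 0.0049 by camera and adjusted p = 0.235 with an estimated correlation. Of 12 measured members 2 rose, 0 fell and 10 did not pass, and 5 rose and 0 fell adjusted over the list alone. MT2A (1.65, adjusted p = 0.0076), a metal-binding protein, and HMOX1 (1.82, adjusted p = 0.0442), heme oxygenase, rose.

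Glucocorticoid targets went both ways (camera adjusted p = 0.15). Of 11 measured members 3 rose, 2 fell and 6 did not pass, and 4 rose and 2 fell adjusted over the list alone. PDK4 was among the rises, and PER1 and DUSP1 (−1.33, adjusted p = 0.000539), a phosphatase of MAP kinases, were the falls. Myogenic regulators were not called (camera adjusted p = 0.995, median −0.15, mean 0.16, upward test). Of 15 measured members 3 rose, 0 fell and 12 did not pass, and 3 rose and 1 fell adjusted over the list alone. The rises were GADD45A (1.56, adjusted p = 0.00504), CDKN1A and RRAD (2.27, adjusted p = 0.022). In the sarcomere load response (camera adjusted p = 0.0658) KLHL40 (1.24, adjusted p = 0.0107) and XIRP1 (2.30, adjusted p = 0.0127) rose and LMOD2 (−0.59, adjusted p = 0.00684) fell. Of 14 measured members 2 rose, 1 fell and 11 did not pass, and 3 rose and 1 fell adjusted over the list alone. Among ribosomal protein genes (camera adjusted p = 0.231) RPL22L1 (0.74, adjusted p = 0.0342) rose. Of 82 measured members 1 rose, 0 fell and 81 did not pass, and 0 rose and 0 fell adjusted over the list alone. The replicate block called glucocorticoid targets (adjusted p = 0.0225, range over the 7 alternatives 0.0225 to 0.639) and the sarcomere load response (adjusted p = 0.0451, range over the 7 alternatives 0.00542 to 0.611). With an estimated correlation under the block adjusted p was 0.401 and 0.662.

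Extracellular matrix genes ranked higher, with adjusted p = 0.00753 by camera and adjusted p = 0.639 with an estimated correlation. None of 19 measured members changed, and 3 rose and 0 fell adjusted over the list alone. All 19 fold changes were positive, with FN1, fibronectin, at 1.32 (adjusted p = 0.0834). The library active post 11 stood apart in fibroblast and macrophage markers. Their mean log2 CPM was 8.10 and 3.06 there, against 6.04 and 1.28 in the next highest library of its group. Macrophage and monocyte markers ranked higher beside the matrix genes, with adjusted p = 0.0465 by camera and adjusted p = 0.639 with an estimated correlation. None of 9 measured members changed, and 0 rose and 0 fell adjusted over the list alone. CD68, a macrophage lysosomal protein, was at 1.26 (adjusted p = 0.174). Without active post 11, adjusted p was 0.288 for matrix, 0.626 for macrophage markers and 0.0928 for ER stress. With the replicate block the macrophage call was lost (adjusted p = 0.229, range over the 7 alternatives 0.0181 to 0.639).

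Markers of other cells and of fibre types gave no other call. Camera adjusted p was 0.995 for slow and 0.866 for fast fibre genes, 0.995 for endothelial, 0.313 for fibroblast and 0.274 for adipocyte genes. It was 0.252 for neutrophil, 0.44 for erythrocyte, 0.477 for T cell, 0.208 for smooth muscle and 0.663 for keratinocyte genes. PECAM1, an endothelial adhesion molecule, rose (0.74, adjusted p = 0.0402) as 1 of 8 endothelial markers (1 rose and 0 fell adjusted over the list alone). ACTA2, smooth muscle actin, rose (1.73, adjusted p = 0.0388) as 1 of 7 smooth muscle markers (2 rose and 0 fell adjusted over the list alone). None changed of 9 slow fibre, 11 fast fibre, 8 fibroblast, 4 adipocyte, 6 neutrophil, 4 erythrocyte, 2 T cell and 1 keratinocyte markers. Adjusted over the list alone, 2 adipocyte markers rose and 1 T cell marker fell. Median and mean differed in sign for slow fibre (−0.04 and 0.02) and fast fibre genes (−0.05 and 0.08). The test differed from both for endothelial (0.01 and 0.03, downward test) and neutrophil genes (−0.35 and −0.36, upward test). The genes given with their own value above lay on the stated side of the active pre mean in 6 of 6 libraries, except JUNB, MT2A, RRAD and CD68 in 5 of 6, and FN1 in 4 of 6.

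The replicate block in the 4 complete pairs called 51 genes and ended 43 of 56 calls of named genes, among them NR4A3 (adjusted p = 0.0918, range 1.23e-15 to 0.0918), HK2 (adjusted p = 0.0556, range 1.22e-07 to 0.0556), PDK4 (adjusted p = 0.0783, range 5.39e-05 to 0.0783) and VEGFA (adjusted p = 0.0857, range 3.75e-09 to 0.0857). Over the 18 alternatives behind these ranges their log2 fold changes ran from 5.87 to 8.28 for NR4A3, 3.01 to 3.87 for HK2, 2.89 to 3.42 for PDK4 and 1.60 to 2.05 for VEGFA. The samples of the contrast alone gave 609 genes. Leaving out 1 replicate number gave 599 genes without number 6, 604 without 10 and 693 without 7, and leaving out the library active post 6 alone gave 657. Without active pre 4, active post 11 and inactive post 4 together, nuclear oxidative phosphorylation was no longer called (adjusted p = 0.0714), and insulin signalling (0.0289), sarcomere load (0.00542), ribosomal protein (0.00145) and neutrophil genes (0.00701) were.

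After a day of inactivity, exercise was followed by higher transcripts of NR4A3, PPARGC1A, HK2, VEGFA and TNFRSF12A, and by lower ones of NR1D1, PER1 and MSTN. NR4A3 rose from 5.71 ± 4.55 to 482 ± 267 CPM (SD, n = 6 and 7), a log2 fold change of 6.38 ± 0.90 (adjusted p = 6.89e-05). PPARGC1A rose from 41.6 ± 10.8 to 464 ± 193 CPM (3.48 ± 0.37, adjusted p = 3.06e-06) and HK2 from 8.91 ± 5.14 to 82.7 ± 51.2 CPM (3.22 ± 0.58, adjusted p = 0.000737). TNFRSF12A, the receptor of the cytokine TWEAK, rose from 4.99 ± 0.867 to 57.6 ± 38 CPM (3.53 ± 0.51, adjusted p = 8.61e-05). MSTN, the myostatin gene that restrains muscle growth, fell from 8.24 ± 3.07 to 2.41 ± 1.14 CPM (−1.77 ± 0.31, adjusted p = 0.000631).

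NR1D1 fell from 82.3 ± 33.6 to 17.5 ± 3.4 CPM (−2.23 ± 0.20, adjusted p = 2.83e-07) and PER1 from 173 ± 42.8 to 59.7 ± 19.2 CPM (−1.54, adjusted p = 6.89e-05). VEGFA rose from 151 ± 49.4 to 577 ± 181 CPM (1.93, adjusted p = 7.08e-05). PDK4, at 109.5 ± 104 before and 362 ± 213 CPM after exercise, did not pass (1.72 ± 0.62, adjusted p = 0.087). For NR4A3, PPARGC1A, HK2 and TNFRSF12A, 7 of 7 inactive post libraries lay above the highest inactive pre library. VEGFA lay above it in 6 of 7 and PDK4 in 4 of 7. For NR1D1, PER1 and MSTN 7 of 7 lay below the lowest. On GRCh38, TNFRSF12A is ENSG00000006327, chromosome 16, 3018445 to 3022383, and MSTN is ENSG00000138379, chromosome 2, 190055697 to 190062729.

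With edgeR's quasi-likelihood test 1325 of 15260 genes changed, 910 upward and 415 downward, with 371 and 66 of these by at least 2-fold. The replicate block raised the count to 2218 (1382 upward and 836 downward). Rises made up 68.7% of the calls with TMM and 59.9% with upper-quartile factors. Large rises beside those above were in MAFF (5.38 ± 0.79, adjusted p = 9.36e-05), SLC16A6 (4.58 ± 0.70, adjusted p = 0.000137) and PRODH (3.51 ± 0.59, adjusted p = 0.000393). SLC30A2 (3.48 ± 0.45, adjusted p = 2.42e-05) and GEM (3.65 ± 0.71, adjusted p = 0.00131), a small GTPase, rose as well. SIK1B (4.13, adjusted p = 0.000103) and SIK1 (3.72, adjusted p = 0.00454) also rose, uncertain for the reads they share. Among the largest falls were GADD45G (−2.76 ± 0.47, adjusted p = 0.000436), HES1 (−2.30 ± 0.24, adjusted p = 2.78e-06) and GAB1 (−1.95 ± 0.23, adjusted p = 8.52e-06). TCF15 (−1.86 ± 0.25, adjusted p = 3.03e-05), SLC38A4 (−1.82 ± 0.45, adjusted p = 0.00993), an amino acid transporter, and LRRC3B (−1.66 ± 0.39, adjusted p = 0.00746) fell too. GLCCI1 (−1.63, adjusted p = 0.000137) and CSF3 (−1.76, adjusted p = 0.0405), which encodes a growth factor of granulocytes, completed them.

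Immediate early genes ranked higher, with adjusted p = 1.79e-05 by camera and adjusted p = 0.305 with an estimated correlation. Of 20 measured members 11 rose, 1 fell and 8 did not pass, and 12 rose and 1 fell adjusted over the list alone. Beside NR4A3, MYC (2.54, adjusted p = 0.000146), a driver of cell growth, and NR4A2 (1.81, adjusted p = 0.000558) rose. Angiogenesis genes again had the smallest list p, with adjusted p = 5.39e-08 by camera and adjusted p = 0.162 with an estimated correlation. Of 16 measured members 9 rose, 0 fell and 7 did not pass, and 11 rose and 0 fell adjusted over the list alone. VEGFA, KDR (1.37, adjusted p = 0.000226) and APLN (1.5, adjusted p = 0.000786), the apelin gene, were among the rises. Clock genes ranked lower, with adjusted p = 0.000777 by camera and adjusted p = 0.305 with an estimated correlation. Of 19 measured members 3 rose, 7 fell and 9 did not pass, and 3 rose and 10 fell adjusted over the list alone. NR1D1, PER1 and CIART (−1.07, adjusted p = 0.000103) were among the falls. The sarcomere load response, genes of structural proteins that react to mechanical strain, ranked higher, with adjusted p = 0.0011 by camera and adjusted p = 0.305 with an estimated correlation. Of 14 measured members 8 rose, 0 fell and 6 did not pass, and 8 rose and 1 fell adjusted over the list alone. KLHL40 (1.57, adjusted p = 0.00101), XIRP1 (2.72, adjusted p = 0.00271) and ABRA (1.53, adjusted p = 0.00374) rose. ATF4 and ER stress genes ranked higher, with adjusted p = 0.0241 by camera and adjusted p = 0.334 with an estimated correlation. Of 10 measured members 3 rose, 0 fell and 7 did not pass, and 3 rose and 0 fell adjusted over the list alone. The rises were DDIT3 (1.07, adjusted p = 0.00162), HSPA5 (0.38, adjusted p = 0.00454) and XBP1 (0.40, adjusted p = 0.0408).

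Heat shock genes ranked higher, with adjusted p = 0.0339 by camera and adjusted p = 0.562 with an estimated correlation. Of 15 measured members 2 rose, 1 fell and 12 did not pass, and 3 rose and 1 fell adjusted over the list alone. HSPA5 and BAG3 (0.52, adjusted p = 0.0161), a cochaperone, rose and DNAJB1 (−0.44, adjusted p = 0.0377) fell. The replicate block lost that list call (adjusted p = 0.0616, range over the 7 alternatives 0.00593 to 0.562). Regulators of mitochondrial biogenesis were not called as a list (camera adjusted p = 0.122). Of 15 measured members 4 rose, 0 fell and 11 did not pass, and 5 rose and 0 fell adjusted over the list alone. PPARGC1A, PERM1 (1.15, adjusted p = 0.00121) and PPRC1 (0.83, adjusted p = 0.00285) rose. Oxidative phosphorylation genes were not called (camera adjusted p = 0.186 nuclear and 0.2 mitochondrial genome). None of the 78 nuclear and 13 mitochondrial-genome members changed, over all genes or adjusted over the list alone. Fat oxidation genes and PPAR targets were not called (camera adjusted p = 0.302, median −0.02, mean 0.25, upward test). None of 23 measured members changed, and 0 rose and 0 fell adjusted over the list alone. The replicate block called PDK4 (log2 fold change 2.10, adjusted p = 0.0197, range over 18 alternatives 0.0138 to 0.248). It also called ANGPTL4, at 2.34 (adjusted p = 0.0671) without the block and 2.59 (adjusted p = 0.0138, range 0.0116 to 0.213) with it. Glucose uptake and glycolysis genes were not called (camera adjusted p = 0.317). Of 27 measured members 2 rose, 1 fell and 24 did not pass, and 2 rose and 1 fell adjusted over the list alone. HK2 and PFKFB2 (1.22, adjusted p = 0.0293) rose, and PDP1, the phosphatase that activates pyruvate dehydrogenase, fell (−0.5, adjusted p = 0.0473).

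Insulin signalling genes were not called (camera adjusted p = 0.355). Of 17 measured members 4 rose, 2 fell and 11 did not pass, and 4 rose and 2 fell adjusted over the list alone. FOXO1 (1.86, adjusted p = 0.000143), RHEB (0.68, adjusted p = 0.0006) and IRS2 (1.93, adjusted p = 0.000956) rose. Atrophy genes were not called (camera adjusted p = 0.0814). Of 14 measured members 5 rose, 1 fell and 8 did not pass, and 6 rose and 1 fell adjusted over the list alone. FOXO1 and CDKN1A (1.72, adjusted p = 0.00107) rose and MSTN fell. In the autophagy list (camera adjusted p = 0.607) GABARAPL1 (1.16, adjusted p = 0.000353) rose. Of 14 measured members 1 rose, 0 fell and 13 did not pass, and 1 rose and 0 fell adjusted over the list alone. Cytokine genes moved both ways (camera adjusted p = 0.131). Of 12 measured members 4 rose, 2 fell and 6 did not pass, and 5 rose and 3 fell adjusted over the list alone. IL6R (1.73, adjusted p = 0.000242) and CCL2 (1.74, adjusted p = 0.00493) rose and NFKBIA (−1.25, adjusted p = 0.0014) fell.

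Myogenic regulators were not called (camera adjusted p = 0.118). Of 15 measured members 3 rose, 1 fell and 11 did not pass, and 3 rose and 2 fell adjusted over the list alone. RRAD (2.62, adjusted p = 0.00591) and GADD45A (1.36, adjusted p = 0.00927) rose. In the glucocorticoid list (camera adjusted p = 0.366) FKBP5 (1.79, adjusted p = 0.0148), a chaperone of the glucocorticoid receptor, rose, and PER1 and DUSP1 (−1.19, adjusted p = 0.000651) fell. Of 11 measured members 1 rose, 2 fell and 8 did not pass, and 5 rose and 2 fell adjusted over the list alone. Ribosomal protein genes were not called (camera adjusted p = 0.118). None of 82 measured members changed, and 0 rose and 0 fell adjusted over the list alone. Among metallothionein and redox genes (camera adjusted p = 0.0814) SRXN1 (0.88, adjusted p = 0.0103), a sulfiredoxin, rose. Of 12 measured members 1 rose, 0 fell and 11 did not pass, and 4 rose and 0 fell adjusted over the list alone. The replicate block called this list (adjusted p = 0.0203, range over the 7 alternatives 0.0203 to 0.486, and adjusted p = 0.294 with an estimated correlation under the block).

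Extracellular matrix genes ranked higher, with adjusted p = 0.000107 by camera and adjusted p = 0.562 with an estimated correlation. Of 19 measured members 3 rose, 0 fell and 16 did not pass, and 4 rose and 0 fell adjusted over the list alone. The rises were the basement membrane collagens COL4A1 (0.98, adjusted p = 0.0182) and COL4A2 (0.80, adjusted p = 0.0464) and TNC (2.28, adjusted p = 0.027), tenascin. Markers of other cells ranked higher beside them. Fibroblast markers did so with adjusted p = 0.0389 by camera and adjusted p = 0.626 with an estimated correlation. None of 8 measured members changed, and 0 rose and 0 fell adjusted over the list alone. Macrophage and monocyte markers did so with adjusted p = 0.0108 by camera and adjusted p = 0.562 with an estimated correlation. Of 9 measured members 1 rose, 0 fell and 8 did not pass, and 7 rose and 0 fell adjusted over the list alone. CD68 rose (1.81, adjusted p = 0.0315). Neutrophil markers did so with adjusted p = 0.0233 by camera and adjusted p = 0.562 with an estimated correlation. None of 6 measured members changed, and 4 rose and 0 fell adjusted over the list alone. The library inactive post 4 held high fibroblast and macrophage markers, 2.61 and 2.40 log2 units above the median of the other libraries of its group. Without it adjusted p was 0.203 for fibroblast, 0.0974 for macrophage and 0.0852 for neutrophil markers, and 0.00993 for matrix genes. Mitochondrial regulators (0.0265) and atrophy genes (0.0265) were then called.

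Other marker lists gave no call. Camera adjusted p was 0.2 for slow fibre, 0.627 for fast fibre, 0.627 for endothelial and 0.862 for adipocyte genes. For erythrocyte genes it was 0.376, for T cell 0.607, for smooth muscle 0.0921 and for keratinocyte genes 0.759. PECAM1 (0.89, adjusted p = 0.00886) rose as 1 of 8 endothelial markers (1 rose and 0 fell adjusted over the list alone). ACTA2 (1.80, adjusted p = 0.023) and TAGLN (1.29, adjusted p = 0.0381) rose as 2 of 7 smooth muscle markers (3 rose and 0 fell adjusted over the list alone). None changed of 9 slow fibre, 11 fast fibre, 4 adipocyte, 4 erythrocyte, 2 T cell and 1 keratinocyte markers, over all genes or adjusted over the list alone. The genes given with their own value above lay on the stated side of the inactive pre mean in 7 of 7 libraries, except PDK4, PRODH, SIK1, XIRP1, ABRA, DDIT3, HSPA5, BAG3, PERM1, ANGPTL4, IRS2, GABARAPL1, RRAD and FKBP5 in 6 of 7.

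Leaving out 1 replicate number gave 753 genes without number 7, 865 without 10, 866 without 11 and 869 without 6, and no single library left out moved the count by more than 1.5 times. The call of PDP1 held in 8 of 18 alternatives, whose adjusted p ranged from 0.00629 to 0.115.

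**Figure D2:**
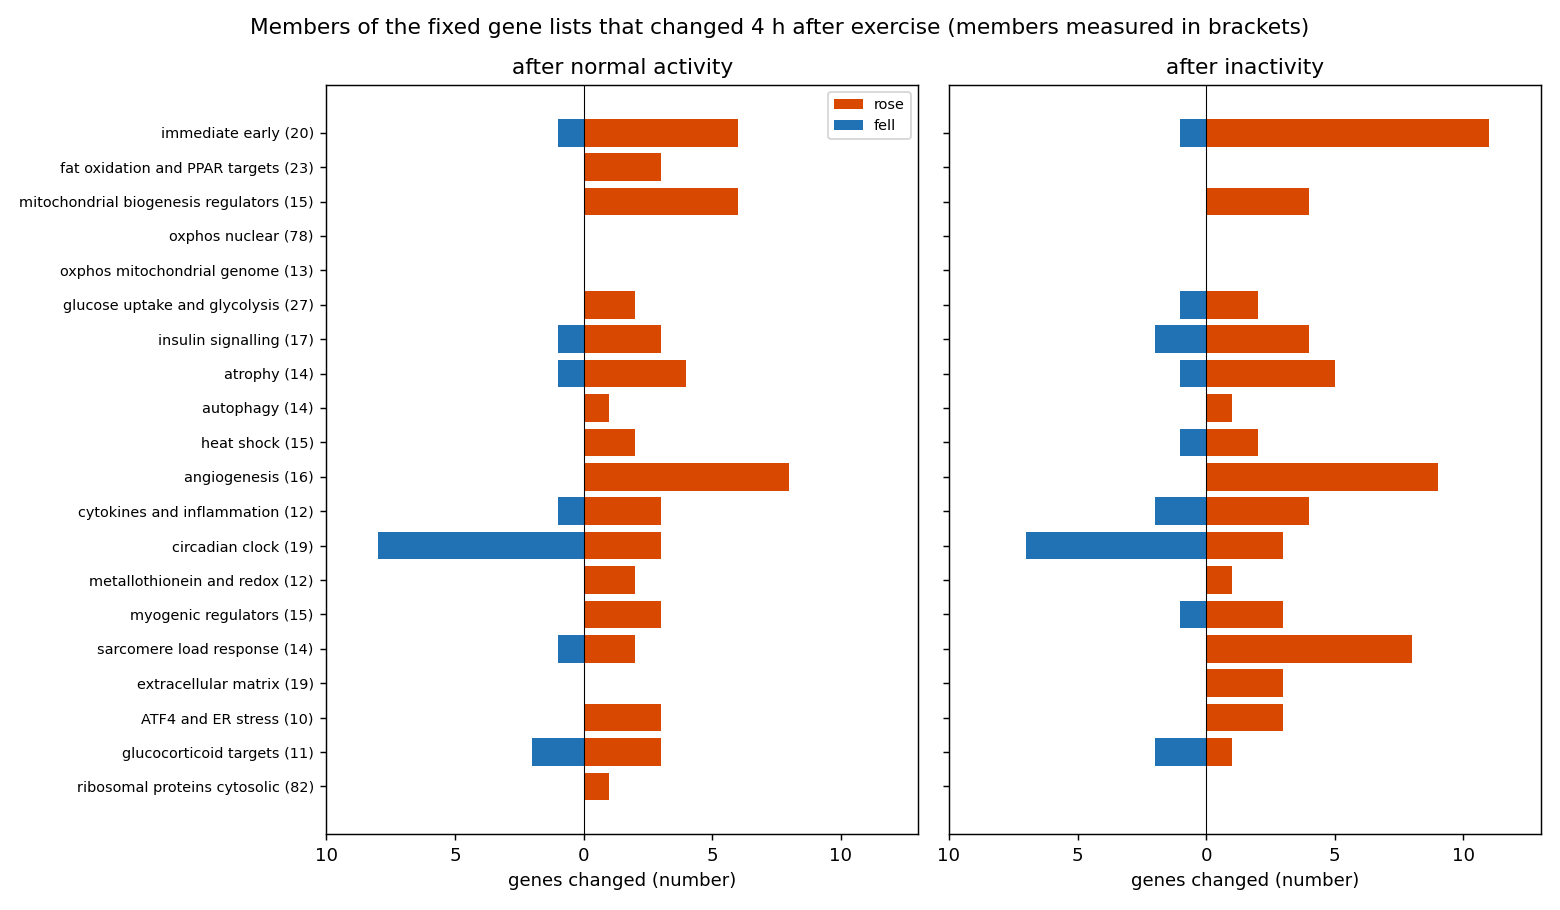
Number of members of each of the 20 pathway lists that rose (bars to the right) or fell (bars to the left) after exercise on each day, with the number of measured members in brackets. Angiogenesis had 8 and 9 rises of 16, and clock genes 8 and 7 falls of 19.

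Across genes, the exercise responses of the 2 days ran in parallel. NR4A3 (6.36 and 6.38), MAFF (5.54 and 5.38) and PPARGC1A (3.69 and 3.48) had log2 fold changes that differed by less than their standard errors on the active and inactive day. The falls of NR1D1 (−1.78 and −2.23), HES1 (−1.79 and −2.30) and GADD45G (−2.05 and −2.76) were larger in value on the inactive day, with differences that did not pass (adjusted p = 0.9999 for each). The log2 fold changes correlated with r = 0.677 over 15260 genes (covariance 0.141), which are not independent replicates, and no library was shared. A difference between replicate numbers alike in every group would give a covariance of −0.00233 with no change. A response particular to a number is not covered by that value. Of the 1628 genes that changed on either day, 781 changed on both, 559 upward, 222 downward and 0 in opposite directions. Independent lists would share 44.3 and 9.27, which leaves out any tie between same-numbered libraries. A further 303 were called on the active day alone and 544 on the inactive day alone. Of the 1628, 99.5% had fold changes of the same sign, and the principal-axis slope of inactive on active fold changes was 1.07, and 1.002 to 1.14 when 1 number was left out. Without replicate number 6, 7 or 10, the genes called on both days numbered 416, 455 and 421.

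**Figure D3:**
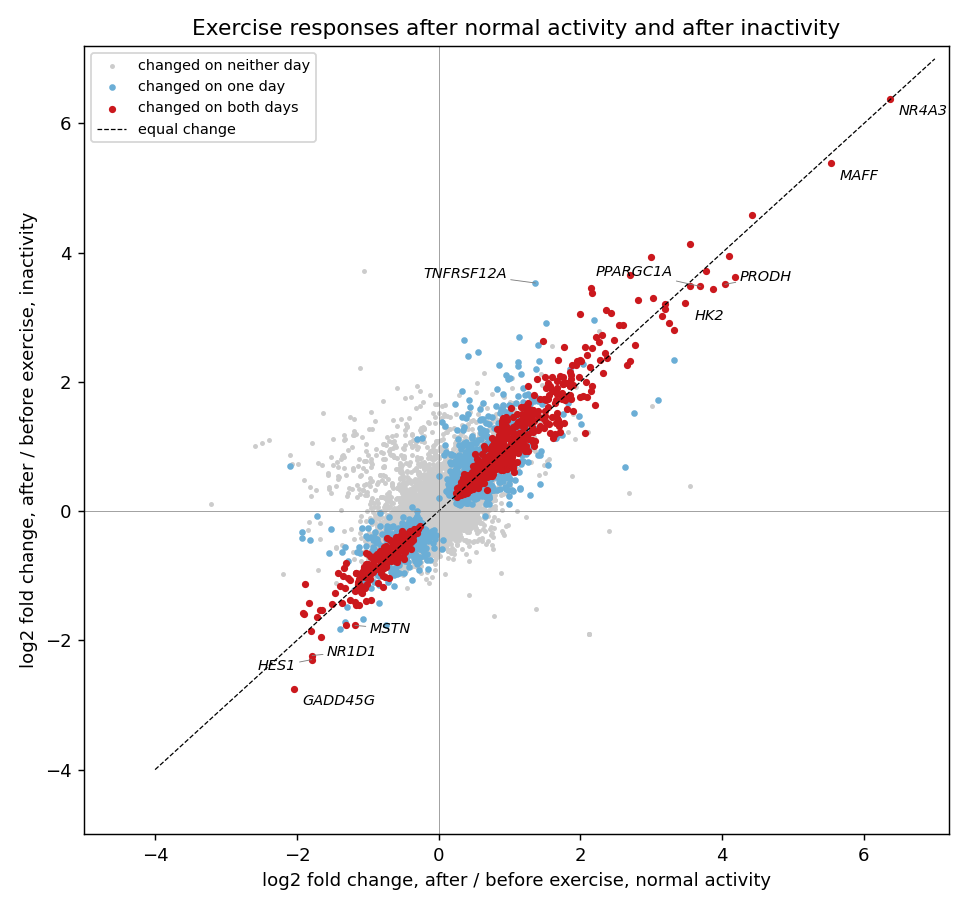
Log2 fold change after exercise on the inactive day (vertical) against the active day (horizontal), 1 point per gene, coloured by whether the gene changed on neither, 1 or both days, with a dashed line of equal change. NR4A3 lies at 6.36 and 6.38, and the 781 genes that changed on both days follow the line; 1 gene lies outside the axes.

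Whether the response depended on the day before was tested as the difference of the 2 responses, inactive minus active. No single gene passed. TNFRSF12A, which went from 18.8 ± 14.1 to 48.4 ± 24 CPM on the active day and from 4.99 ± 0.867 to 57.6 ± 38 CPM on the inactive day, had a difference of 2.17 ± 0.66 log2 units (adjusted p = 0.9999 by edgeR). PDK4, with a rise on the active day, had a difference of −1.37 ± 0.85 (adjusted p = 0.9999). As groups, immediate early and sarcomere load genes ranked higher in this difference, and ribosomal protein genes lower, each by a small median shift. With an estimated correlation adjusted p was 0.707, 0.707 and 0.709. The sarcomere load and ribosomal calls mainly mirrored the pre-exercise gap, and the replicate block ended both.

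edgeR called 0 genes, with 257 at an unadjusted p under 0.05 where 763 would be so by chance. DESeq2 called 0 with 291 at that level, and the replicate block called 0 with 261. The 763 holds for independent libraries, whereas same-numbered ones correlated. Counts below it therefore do not show that the responses were alike. Among genes with the smallest p, MTND1P23 had a difference of 11.62 ± 2.97. It is a copy of a mitochondrial gene whose reads may be shared, and its blocked difference was −1.09. ZNF462, a zinc finger gene, was at −0.73 ± 0.20. Differences, with ranges over the alternatives, were positive for the T cell genes CD247 (2.79, 0.76 to 3.09) and CD3E (3.55, −0.16 to 4.26). They were so for the cytotoxic granule gene PRF1 (1.92, 0.63 to 2.34) and the immunoglobulin gene IGHM (3.59, 0.62 to 4.14). The small structural RNAs RN7SK (−2.90 ± 1.01) and RPPH1 (−2.40 ± 0.84) had negative ones. So had 5.8S rRNA (−4.03), which is uncertain because 4 copies are near-identical. All of these had an adjusted p of at least 0.9999. The median standard error of a difference was 0.24 log2 units.

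Of 31 lists, 7 were called by camera, and none of their members passed over all genes. Immediate early genes ranked higher (adjusted p = 0.00622 by camera and 0.707 with an estimated correlation). Their median difference was 0.33, 16 of 20 members were positive, and EGR2 stood at 1.40, EGR3 at 1.12 and NR4A2 at 0.91. The sarcomere load response also ranked higher (adjusted p = 0.0213 by camera and 0.707 with an estimated correlation). Its median was 0.27, with 11 of 14 positive and ANKRD1, a titin-binding stress protein, at 1.16. The replicate block lost that call (adjusted p = 0.208, range over the 7 alternatives 5.1e-05 to 0.707). Myogenic regulators ranked higher (adjusted p = 0.038 by camera and 0.707 with an estimated correlation). Their median was 0.20 with 11 of 15 positive, CHRNA1, an acetylcholine receptor subunit, at 1.37 and the embryonic myosin MYH3 at 1.41. Atrophy genes ranked lower (adjusted p = 0.0387 by camera and 0.707 with an estimated correlation). They had a median of −0.21 and 3 of 14 positive, and the block lost the call (adjusted p = 0.245, range over the 7 alternatives 0.03 to 0.749). Ribosomal protein genes ranked lower (adjusted p = 5.94e-06 by camera and 0.709 with an estimated correlation). They had a median of −0.07 and 7 of 82 positive, and the block lost the call (adjusted p = 0.153, range over the 7 alternatives 1.65e-18 to 0.709).

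Neutrophil markers ranked higher (adjusted p = 0.0387 by camera and 0.709 with an estimated correlation). Their median was 1.98, with 6 of 6 positive and S100A8 at 2.24. Without active pre 4, active post 11 and inactive post 4 the neutrophil median turned to −0.0706 (adjusted p = 0.73, range over the 7 alternatives 0.000854 to 0.823). Erythrocyte markers ranked higher (adjusted p = 0.0283 by camera and 0.707 with an estimated correlation). Their median was 2.39, with 4 of 4 positive and HBA2, uncertain beside its copy HBA1, at 2.43. The block lost the erythrocyte call (adjusted p = 0.471, range over the 7 alternatives 0.0179 to 0.784). The library active pre 4 stood apart in T cell, neutrophil and erythrocyte markers, 3.95, 4.17 and 3.40 log2 units above the median of the others of its group. Without it adjusted p was 0.823 for neutrophil, 0.257 for erythrocyte, 0.0798 for sarcomere load and 0.257 for atrophy genes. The 4 lists called without it were ribosomal proteins (1.65e-18), immediate early genes (0.0345), myogenic regulators (0.00809) and fat oxidation (0.0345). With the replicate block 4 further lists were called: glucose uptake (adjusted p = 0.0418, range 0.0418 to 0.987), matrix (0.0323, range 2.97e-06 to 0.861), fibroblast (0.00605, range 0.000308 to 0.803) and T cell genes (0.0239, range 0.0239 to 0.802). With an estimated correlation under the block adjusted p for these 4 was 0.76 to 0.82.

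**Figure D4:**
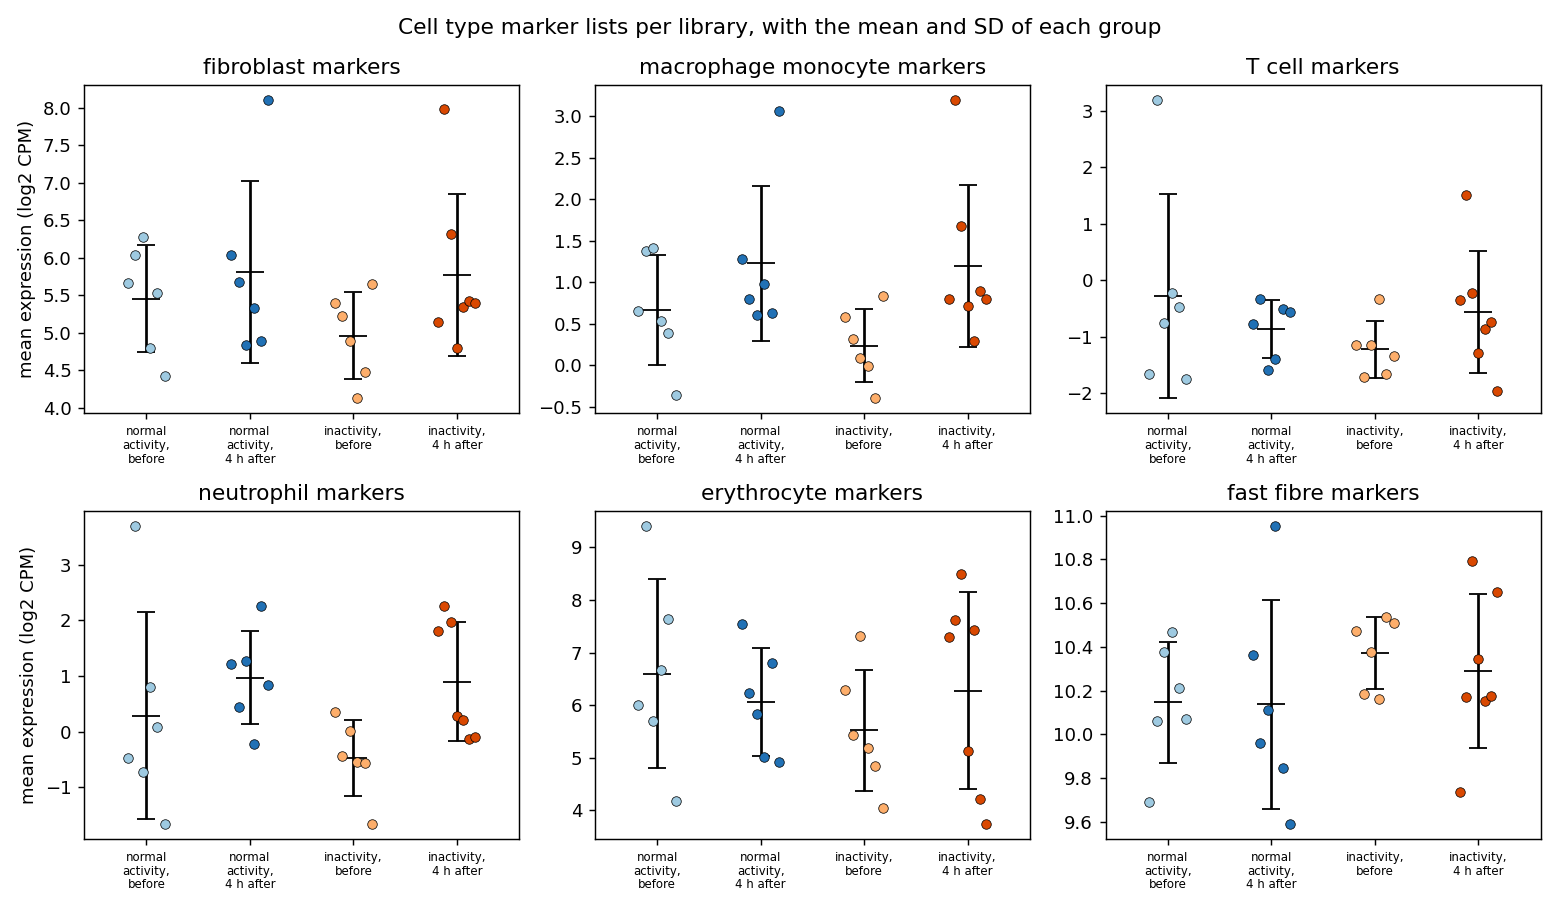
Mean log2 CPM of 6 marker lists in each library (points), by group, for fibroblast, macrophage and monocyte, T cell, neutrophil, erythrocyte and fast fibre genes. The T cell list reached 3.19 in active pre 4 and the fibroblast list 8.10 in active post 11.

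Adjusted over the list alone, 2 of 2 T cell markers rose and 0 fell. The other 24 lists had camera adjusted p from 0.0547 to 0.984. Median, mean and test differed in sign for heat shock (0.03, −0.02 and down), cytokines (−0.01, −0.000199 and up) and clock genes (0.10, −0.02 and down).

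Before exercise, no single gene passed. As groups, by camera, sarcomere load, heat shock and matrix genes ranked lower after inactivity, and glycolysis, nuclear respiratory chain and ribosomal protein genes higher. With an estimated correlation adjusted p for these lists was 0.339 to 0.66, and the replicate block ended the calls of sarcomere load, heat shock and ribosomal proteins. PDP1 (GRCh38, ENSG00000164951, chromosome 8, 93857807 to 93926066) was at 53.5 ± 9.26 CPM in active pre and 93.7 ± 26.4 CPM in inactive pre, a log2 fold change of 0.81 ± 0.16 (adjusted p = 0.764 by edgeR). TNFRSF12A was at 18.8 ± 14.1 and 4.99 ± 0.867 CPM (−1.92 ± 0.49, adjusted p = 0.9996). Next in p were BIN3 (−0.57 ± 0.13) and APLN (−1.07 ± 0.28), with the same adjusted p as TNFRSF12A.

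edgeR called 0 genes, with 513 at an unadjusted p under 0.05 where 763 would be so by chance. DESeq2 called 1 gene, PDP1 (adjusted p = 0.027), with 552 at that level. The replicate block called 3, with 1131 at that level, above the 763 of chance. They were PDP1 (adjusted p = 0.0252), LBP, for a lipopolysaccharide binding protein (log2 fold change −2.35, adjusted p = 0.0135), and C4orf54 (0.71, adjusted p = 0.0343). LBP and C4orf54 were chosen after their values were seen. Over 17 alternatives the adjusted p ranged from 0.0252 to 0.99998 for PDP1, from 0.0135 to 0.99998 for LBP and from 0.0343 to 0.99998 for C4orf54. PDP1, BIN3, TNFRSF12A and APLN lay on the stated side of the active pre mean in 6 of 6 inactive pre libraries.

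Camera called 14 of 31 lists. Glucose uptake and glycolysis genes ranked higher (adjusted p = 8.41e-05 by camera and 0.339 with an estimated correlation). Of 27 members 17 were positive, and 2 rose and 0 fell adjusted over the list alone. Beside PDP1, PPP1R3C, which targets a phosphatase to glycogen, was at 0.51 and PGAM2, a glycolytic mutase of muscle, at 0.38. Nuclear oxidative phosphorylation genes ranked higher (adjusted p = 3.09e-05 by camera and 0.66 with an estimated correlation). They were positive in 72 of 78 with a median of 0.08, COX7A1 at 0.20. Ribosomal protein genes ranked higher (adjusted p = 2.38e-07 by camera and 0.608 with an estimated correlation). They were positive in 74 of 82 with a median of 0.07, RPS15A at 0.19. Fast fibre genes ranked higher (adjusted p = 0.00939 by camera and 0.339 with an estimated correlation). All 11 were positive, TNNI2, a fast troponin, at 0.18.

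Sarcomere load (12 of 14 negative, ANKRD2 at −1.40) and heat shock genes ranked lower, with adjusted p = 0.000103 and 0.000117 by camera. Both were at 0.339 with an estimated correlation. All 15 heat shock genes were negative, the small chaperones HSPB1 at −0.62 and CRYAB at −0.45. ATF4 and ER stress genes (7 of 10 negative) and immediate early genes (18 of 20) ranked lower. Adjusted p was 0.0189 and 0.0318 by camera and 0.339 and 0.608 with an estimated correlation. Myogenic regulators ranked lower, with adjusted p = 0.0367 by camera and adjusted p = 0.586 with an estimated correlation. Of these 11 of 15 were negative, CHRNA1 at −1.44 and MYH3 at −1.5.

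Matrix genes and markers of other cells ranked lower after inactivity. Extracellular matrix did so with adjusted p = 0.00019 by camera and adjusted p = 0.608 with an estimated correlation (median −0.38, TNC at −1.36). Fibroblast (median −0.63) and macrophage markers (−0.51) did so with adjusted p = 0.0483 and 0.0344 by camera (each 0.657 with an estimated correlation). Neutrophil (median −1.98, S100A8 at −2.27) and erythrocyte markers (median −1.62) did so with adjusted p = 0.00409 and 0.0189 by camera. Both were at 0.586 with an estimated correlation. The active pre group holds active pre 4, whose T cell markers stood at 3.19 mean log2 CPM against −0.23 in the next highest library. Without active pre 4, adjusted p was 0.199 for immediate early, 0.239 for fibroblast, 0.223 for macrophage, 0.377 for neutrophil and 0.296 for erythrocyte genes. Then 9 lists were called, with glycolysis at 0.00011, sarcomere load at 0.000372 and heat shock at 0.00011.

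With the replicate block 6 of the 14 lists lost their call: ribosomal proteins (adjusted p = 0.419, range over the 7 alternatives 2.25e-25 to 0.608), sarcomere load (0.0642, 4.44e-05 to 0.339), heat shock (0.054, 4.44e-05 to 0.339), ER stress (0.0642, 0.0136 to 0.339), immediate early (0.309, 0.0178 to 0.608) and erythrocyte genes (0.419, 0.0178 to 0.586). It called mitochondrial regulators (adjusted p = 0.0407, range 0.0341 to 0.608) and T cell markers (0.0356, range 0.0356 to 0.652), both with adjusted p = 0.653 with an estimated correlation under the block. The other 17 lists had camera adjusted p from 0.0654 to 0.929. Adjusted over the list alone, 5 of 6 neutrophil and 2 of 2 T cell markers and 1 of 16 angiogenesis genes were lower after inactivity. Median, mean and test differed in sign for fat oxidation (0.00752, −0.09 and down), atrophy (−0.00846, 0.02 and up), autophagy (0.00191, −0.0142 and down) and clock genes (−0.00833, 0.06 and up).

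After exercise, nuclear respiratory chain and glycolysis genes ranked higher by camera and heat shock genes lower after inactivity than after normal activity, while no single gene passed. With an estimated correlation adjusted p was 0.845, 0.438 and 0.438. The smallest p belonged to CEBPB-AS1 (0.70 ± 0.16), antisense to the transcription factor gene CEBPB and uncertain for want of strand information. Next were ZNF646 (−0.28 ± 0.08), SLC35C1 (−0.41 ± 0.11), a fucose transporter, HSPA1B (−0.54 ± 0.16) and ACVR1C (−1.01 ± 0.31), a receptor of the TGF-beta family. All had an adjusted p of at least 0.9999 by edgeR and lay on the stated side of the active post mean in 7 of 7 inactive post libraries. So did PDK4 (−1.16), at 807 ± 380.2 CPM in active post and 362 ± 213 CPM in inactive post. edgeR called 0 genes, with 269 at an unadjusted p under 0.05 where 763 would be so by chance. DESeq2 called 0 with 306 at that level, and the replicate block 0 with 582.

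Camera called 7 lists. Nuclear oxidative phosphorylation genes ranked higher (adjusted p = 1.98e-13 by camera and 0.845 with an estimated correlation). They were positive in 76 of 78 with a median of 0.12, ATP5ME at 0.25 and NDUFB2 at 0.17. Glucose uptake and glycolysis genes ranked higher (adjusted p = 5.11e-05 by camera and 0.438 with an estimated correlation). They were positive in 21 of 27 with a median of 0.19, PGAM2 at 0.48 and PKM, pyruvate kinase, at 0.41. Heat shock genes ranked lower, with adjusted p = 4.07e-06 by camera and adjusted p = 0.438 with an estimated correlation. Their median was −0.18, HSPA1A was at −0.5, and 0 rose and 1 fell adjusted over the list alone. Fat oxidation genes and PPAR targets ranked lower, with adjusted p = 0.00597 by camera and adjusted p = 0.866 with an estimated correlation. Of 23 members 15 were negative, LPL, lipoprotein lipase, at −0.5. Metallothionein and redox genes ranked lower, with adjusted p = 0.0215 by camera and adjusted p = 0.438 with an estimated correlation (median −0.25, MT2A at −0.98). Fast fibre genes ranked higher, with adjusted p = 0.0215 by camera and adjusted p = 0.511 with an estimated correlation. They were positive in 9 of 11, although MYH1, a fast myosin, was at −1.01. The mitochondrial genome ranked higher, with adjusted p = 0.0266 by camera and adjusted p = 0.866 with an estimated correlation, with 12 of 13 positive. The replicate block lost fat oxidation (adjusted p = 0.153, range over the 7 alternatives 0.00181 to 0.866), fast fibre (adjusted p = 0.0842, range 0.019 to 0.511) and the mitochondrial genome (adjusted p = 0.812, range 1.81e-05 to 0.866).

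Markers of other cells were high in 1 library of each post group, active post 11 and inactive post 4. Without active post 11 fibroblast markers were called (adjusted p = 0.0187), and metallothionein (0.0861) and fast fibre genes (0.33) were not. Without inactive post 4 extracellular matrix (adjusted p = 0.000554) and macrophage markers (0.00223) ranked lower, and fat oxidation (0.121) and metallothionein genes (0.138) were not called. The other 24 lists had camera adjusted p from 0.0646 to 0.912. Median, mean and test differed in sign for mitochondrial regulators (0.00846, −0.05 and down), angiogenesis (0.00133, −0.09 and down), ER stress (0.05, −0.12 and down) and smooth muscle genes (−0.11, 0.00659 and up). They also did for fibroblast (−0.12, −0.13 and up), macrophage (0.01, −0.02 and down) and neutrophil genes (0.12, 0.06 and down).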

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

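All tests in this part were chosen only after the results they measure were seen, except the test of the difference of the responses, which was planned. A library was set apart where its gap to the nearest other library of its group, over the range of the group, passed Dixon's 95% limit; chance sets apart about 1 in 20 groups, and 16 of 168 groups of values held such a library.

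Active pre 4, active post 11 and inactive post 4 held high markers of other cells. Mean log2 CPM of T cell markers was 3.19 in active pre 4 (nearest −0.23). Fibroblast and macrophage markers reached 8.10 and 3.06 in active post 11 (nearest 6.04 and 1.28). A lower fibre share that raised all other cells alike would raise endothelial markers as much. Their highest excess over the group median was 0.535 log2 units (inactive post 4, above all others). Neutrophil markers in active pre 4 (4.17) and fibroblast markers in active post 11 (2.77) and inactive post 4 (2.61) lay higher. This argues against an even rise, but a fibre share lowered by added tissue stays open. Erythrocyte markers argue against blood as the source in active post 11, where they lay at −1.31 against the group median (SD of the others 0.958). In inactive post 4 their excess of 1.41 lay within the SD of the others (1.95) while neutrophil and T cell markers, 2.02 and 2.31 over the median, lay above all other libraries, so blood stays open there. In active pre 4 all 3 blood cell lists lay above all other libraries, erythrocyte by 3.40, neutrophil by 4.17 and T cell by 3.95 over the median, which is consistent with blood in the biopsy; a piece of connective tissue in active post 11 and inactive post 4 stays open and was not tested, and no biological explanation was tested.

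Inactive post 4 had the lowest log2 CPM of its group for NR4A3 (4.80, nearest 7.99), PPARGC1A (6.25, nearest 8.55) and VEGFA (7.59, nearest 9.05), and the lowest list means for mitochondrial regulators (4.27, nearest 4.70), glucose uptake and glycolysis (7.66, nearest 8.09), insulin signalling (4.79, nearest 5.19) and autophagy (5.14, nearest 5.43). Dilution by RNA of other cells would lower fibre markers as much as PPARGC1A, but 20 fibre markers had a median deficit of −0.343 log2 units against −2.77 for PPARGC1A, which argues against it. A mixture with pre-exercise RNA alone would give 1 share of post-exercise RNA. The 199 genes that rose gave 15.3% and 43 that fell 72.0%, which argues against it. The gap of −56.7 percentage points had a 95% bootstrap interval of −73.3 to −38.2 (2000 resamples of genes, not libraries). A mixture with dilution as well was not tested. A weaker response in libraries of number 4 may account for it: relative to the fold changes of the other day, the slope was 0.562 in active post 4 over the 1325 genes called on the inactive day, the lowest of its group (others 0.741 to 1.12), and 0.385 in inactive post 4 over the 1084 called on the active day (others 0.868 to 1.09). The labels do not say what the number stands for, so whether these are the same person was not tested.

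Other libraries set apart are given as values. In active pre 4 clock genes had the lowest mean log2 CPM (4.61, nearest 4.82) and sarcomere load genes the highest (8.97, nearest 8.58). Adipocyte markers were highest in inactive pre 3 (5.56, nearest 3.63), and ribosomal protein genes lowest in inactive post 9 (7.68, nearest 7.88). Total counts were highest in active pre 7 (61.4 M, SI prefix mega, nearest 40.7) and active post 11 (61.6 M, nearest 39.3).

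Camera called 7 lists in the difference of the responses. Adjusted p was 5.94e-06 for ribosomal proteins and 0.0387 for atrophy genes, both downward. Upward it was 0.00622 for immediate early, 0.0213 for sarcomere load, 0.0283 for erythrocyte, 0.038 for myogenic and 0.0387 for neutrophil genes. With an estimated correlation these were 0.707 to 0.709.

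Other splits of the samples were drawn 100 times per comparison, the real split included. For the response after normal activity 1 of 100 splits, the real one, gave as many as 1084 genes, and the highest other gave 244. The splits were drawn without regard to the pairing, so they do not exclude chance for paired samples. Of the others 11 parted 4 same-numbered pairs as the real split does, and the highest of those gave 0, but they are too few for a share under 0.05. For the response after inactivity 1 of 100, the real one, gave as many as 1325 and the highest other gave 590, with the same limit. Only 3 others parted 6 pairs as the real split does, too few for a share under 0.05, and they gave 590, 0 and 0. For the difference, the pre-exercise and the post-exercise comparison the real count was 0, which 100 of 100 splits must reach, so the splits say nothing about chance there; the highest others gave 3, 1 and 15.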

How the results depend on the processing

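Alternatives that left out single libraries or the libraries active pre 4, active post 11 and inactive post 4, used a day's own table, or left numbers out of the agreement were chosen after seeing the data. No called gene changed direction in any of the alternatives, and the difference and the post-exercise comparison gave 0 genes in each. The cause was not tested for any change below except stricter thresholds, which lower counts by construction.

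The response after normal activity (1084 genes) gave 480 at adjusted p under 0.01, 340 with a change of at least 1 log2 unit, 609 with the samples of the contrast alone, 614 over all genes of its own table, 51 in complete pairs with the replicate block, and 1803 with the block without the 3 libraries that stand apart. Leaving out 1 number or library gave 599 to 1440. The response after inactivity (1325) gave 651 at 0.01, 437 with 1 log2 unit, 2218 with the replicate block, 2122 with the block in complete pairs and 2590 with the block without the 3 libraries; leaving out 1 number or library gave 753 to 1637. Before exercise (0) DESeq2 called 1 gene and the replicate block 3. Other settings stayed within 1.5 times: DESeq2 1432 and 1673, upper-quartile factors 1025 and 1313, adjusted p under 0.10 1574 and 1878, and, without the 3 libraries, 1181 and 1765 genes on the active and inactive day. No filter gave the same calls.

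The replicate block lost 131 and 26 calls and made 543 and 919 new ones on the active and inactive day. Of named genes it ended the call of AC002996.1 and called SRXN1, TNC, COL4A1 and TAGLN (active), ANGPTL4, PDK4, HMOX1, MT2A, MFAP5 and CD14 (inactive) and PDP1, LBP and C4orf54 (before exercise); it changed no other call of a named gene, and of lists those the report gives. Complete pairs on the active day, with 4 pairs, ended 43 of 56 named calls. Leaving out 1 number ended 15 of 56 named calls on the active day in at least 1 run and 17 of 60 on the inactive day, among them PPARD, HSPA5, XIRP1 and KLHL40 (active) and PFKFB2, COL4A1, FKBP5 and GADD45A (inactive).

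List calls (13, 10, 7, 14 and 7 of 31 for active, inactive, difference, pre and post) fell to 0 in all 5 with an estimated correlation. Ranks gave 10, 10, 11, 13 and 8, and the block 12, 10, 7, 10 and 4. Without active pre 4 they were 14, 10, 4, 9 and 7, without active post 11 12, 10, 9, 14 and 6, without inactive post 4 15, 9, 6, 15 and 8, and without all 3 libraries 13, 11, 7, 11 and 5. In that last setting 1 list turned: neutrophil markers in the difference (median −0.0706, adjusted p = 0.73).

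Agreement of the 2 responses (r = 0.677, 781 genes on both days) was 0.774 over genes with an average log2 CPM of at least 1 and 0.629 by Spearman. Leaving out 1 number gave r from 0.557 to 0.764 and 416 to 994 shared genes, and an adjusted p under 0.01 358 shared genes. In simulated counts at these depths and group sizes 5.41% of 1.5-fold differences of response were recovered, against 37.8 and 27.3% of 1.5-fold responses on the active and inactive day. Depth alone was not varied, so its share in this limit was not tested.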

Other observations

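In this part the test of RN7SK against histone genes was chosen before its result was seen; all others, and the genes named, were chosen after.

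Transporters of the solute carrier families, named by the letters SLC, rose more often than other genes on both days. On the active day 28 of 237 rose where 11.5 would by chance (Fisher's exact test, adjusted p = 0.00734 over 372 tests of 93 families), and on the inactive day 30 of 237 where 14.1 would (adjusted p = 0.0157). Examples, with log2 fold changes on the active and inactive day, were SLC7A5 (1.04 and 1.13) and SLC3A2 (0.90 and 0.93), the chains of a transporter of large neutral amino acids, SLC38A1 (1.67 and 2.02), a glutamine transporter, and SLC25A33 (1.90 and 1.95), a mitochondrial pyrimidine nucleotide carrier. Each passed on both days and lay above the pre-exercise mean in 6 of 6 active post and 7 of 7 inactive post libraries, except SLC38A1 in 5 of 6 on the active day and SLC7A5 and SLC25A33 in 6 of 7 on the inactive day. Falls numbered 11 and 14 where 5.3 and 6.45 would by chance (adjusted p = 0.489 and 0.359), so the odds ratios of falls (2.17 and 2.29) were near those of rises (2.68 and 2.33). Upper-quartile factors gave 22 and 26 rises and DESeq2 29 and 31. Phosphodiesterase genes (PDE), many of which break down cyclic nucleotides, rose in 6 of 21 cases on the active day where 1.02 would by chance (adjusted p = 0.0468; 5 with upper-quartile factors and 6 with DESeq2). On the inactive day 4 of 21 rose where 1.25 would, which did not pass (adjusted p = 0.516). PDE7A (1.08 and 0.99) and PDE10A (1.51 and 2.07) rose on both days, while PDE4D rose on the active day (0.85) and did not pass on the inactive day (0.55, adjusted p = 0.0592). Each lay above the mean in 6 of 6 active post libraries. Of genes typed as long intergenic RNAs, 9 of 487 rose and 9 fell on the active day and 14 rose and 7 fell on the inactive day, and of antisense RNAs 11 and 10 of 582, and 15 and 13.

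The small structural RNAs RN7SK and 5.8S rRNA varied together between libraries of the same group. Within groups, log2 CPM of RN7SK followed that of the 5.8S rRNA copies over 25 libraries (Pearson r = 0.965, Spearman rho = 0.915, r = 0.948 without the 2 libraries farthest from the median). Permutation p was 1e-05 for r, the smallest that 100000 permutations can give, and 3e-05 for rho (adjusted p = 1.5e-05 and 4.5e-05 over 3 relations). The 14 replication-dependent histone genes (mean 5.92 CPM) had r = −0.100 with RN7SK (permutation p = 0.67, r = 0.0131 without the 2 farthest libraries). Their rho was −0.0123 (permutation p = 0.96). Whether their transcripts lacked a poly(A) tail here is unknown, so uneven loss of RNAs without one stays open. So does uneven recovery of short structured RNAs, which was not tested. Either may underlie group differences in RN7SK, RPPH1 and 5.8S rRNA.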
